A study of Mus musculus with 13 samples.

How the data were processed

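RNA from C2C12 myoblasts at 13 time points, 0 to 6.0 h after the return to serum in steps of 0.5 h, had been labelled with biotin and hybridised to 1 Affymetrix mouse expression array each, per the labels' protocols and the probe table. The labels give parallel flasks, 1 sample per time point and no replicate numbers. The deposited values are linear ratios, and per the submitters' processing notes RMA was used, with no version stated. How the authors formed the ratios is not given in the sources used here. In the deposited table, 36540 probe sets had exactly 1 array at a ratio of 1, and in 99.9% of them that array ranked 6 to 8 of 13, which is where the median over 15 arrays would lie if 2 were not used here. Another 4444 probe sets (9.9%) looked as if they had been divided by a common floor, and 3019 probe sets lay under 1 on all 13 arrays. The ratios ranged from 0.0199 to 18.98. A ratio to a per-probe-set reference removes the absolute signal, so no filter on dim probe sets and no comparison of levels between genes could be made, and changes of dim transcripts are compressed to an unknown degree.

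The table held 45101 probe sets. The 64 array controls were left out of every test, which left 45037. Of these, 34945 had 1 gene symbol, 932 had several and 9160 had none in the platform annotation; only those with 1 symbol were named. The gene IDs of 34741 were found in the reference gene table, and 0 symbols changed. They represented 18193 genes, 9010 of them with several probe sets. The rule set beforehand, the probe set with the highest mean, could not be applied to ratios without levels, so the value of a gene is the mean log2 ratio over all probe sets that name only that gene. No pair of arrays held identical values. Correlations between arrays over probe sets ran from -0.432 to 0.649; neighbouring arrays correlated at 0.606 (1.5 and 2.0 h), 0.263 (2.0 and 2.5 h), 0.317 (4.0 and 4.5 h) and 0.43 (4.5 and 5.0 h). Array dates were not given in the sources used here, so no batch could be tested as a block.

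Tests were run on the log2 of the deposited ratio with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3; tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Arrays were grouped into windows by labelled time, all 13 entered 1 fit of the window means, and early minus 0 h and late minus early were the contrasts. The single 0 h array is assumed to vary like the others. A natural cubic spline of time with 4 degrees of freedom gave a moderated F test of any smooth course. A cosine and a sine with a period of 2 h, added to a spline trend of 3 degrees of freedom, gave the test of oscillation. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. The 28 gene lists, the tests, the windows, the alternatives and the rule for named genes were set before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks only whether a list's own genes move in 1 direction. For the oscillation, each list's median F was compared with 10000 permutations of the array order of the trend residuals, one-sided.

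Named genes were, per window comparison, the 12 with the largest rise and the 12 with the largest fall among probe sets past the threshold that name 1 gene. For the smooth course they were the 10 with the smallest p, and for the oscillation the 10 with the smallest p, as fewer than 10 passed. Up to 4 members of each list with the largest change (largest F for the oscillation) and all segmentation clock genes were added. Values are printed at the gene level, so a gene chosen through 1 probe set can miss the threshold.

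The models were tested on simulated data for 45037 probe sets, a part of them changed by known amounts. Early against 0 h recovered 20.9% of changes of 0.5 on the log2 scale, 80.6% of 1 and 97.0% of 2. Late against early recovered 74.6%, 98.5% and 100%, and the smooth course 16.4%, 91.0% and 100% of straight changes of these sizes. Of 44837 unchanged probe sets, 4, 11, 3 and 6 were called in the early, late, smooth and oscillation tests. The simulated noise was independent between arrays and, for a given probe set, had the same spread on every array. These rates therefore need not hold where arrays differ in spread or neighbouring arrays resemble each other. Alternatives were quantile normalization, centring each array on its median, a variance trend with a robust prior, leaving out each array in turn and other windows. Others were a minimum log2 change of 1, a straight line in time, other spline flexibilities and time axes, other periods and trends, and other list tests. The variance trend ran over the mean log2 ratio, as the ratios hold no intensity. It could therefore not check for variance that depends on intensity. Added after the data were examined were fits without floor-scaled probe sets, without the 2.5 to 4.0 h arrays, with 1 mean value per gene and with 1 probe set per gene. Results for 1 gene and some gene families are not reported here, although the counts of named genes and of families include them.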

Results

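C2C12 cells, a line of mouse skeletal muscle precursors (myoblasts), were held for a day in low serum and then returned to serum. RNA was profiled every 0.5 h on Affymetrix mouse expression arrays. The study looked for genes whose expression oscillates, as part of work on the formation of somites, the embryonic segments that give rise to muscle and skeleton. The 13 arrays analysed here covered 0 to 6.0 h, with 1 array per time point and no replicates; later samples were not analysed here. By the labelled time alone, the arrays were placed in windows: 0 h (1 array), early (0.5 to 2.0 h, 4 arrays), middle (2.5 to 4.0 h, 4 arrays) and late (4.5 to 6.0 h, 4 arrays). Values were deposited as ratios to a reference value of each probe set, so they carry changes and no absolute level. The number of arrays limits the precision. Median ratios of the 13 arrays lay between 0.977 and 1.00. The residual SD within windows had a median of 0.102 on the log2 scale over 18193 genes. For single genes and probe sets, p-values of the window comparisons measure the spread within windows, which holds technical variation and real change together. Those of the smooth course and the oscillation rest on the spread around a fitted curve. Camera compares a list with the other genes, and the oscillation test of lists permutes the array order. No p-value measures variation between replicates. Changes are given below as log2 differences ± standard error.

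The first comparison asked what the return of serum changed within 2.0 h. By camera, immediate-early transcription factors rose as a group (adjusted p = 1.45e-20), a call that was lost with an estimated correlation between genes (adjusted p = 0.0638). Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, rose by 4.50 ± 0.38 (adjusted p = 7.21e-05) and reached 26.1 times its 0 h level at 2.0 h. Ccn2, a matrix-associated growth regulator, rose by 3.48 ± 0.16 (adjusted p = 3.83e-08), and the nuclear receptor Nr4a1 rose by 3.85 ± 0.58 (adjusted p = 0.00512) with its highest level, 26.0-fold over 0 h, already at 0.5 h. Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 1.40 ± 0.22 (adjusted p = 0.00596) and was 3.53-fold under 0 h at 1.5 h.

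Further large rises were those of Ereg (3.45 ± 0.54), an epidermal growth factor receptor ligand, and of Id3 (2.99 ± 0.27) and Id1 (2.73 ± 0.51), inhibitors of basic helix-loop-helix factors. The zinc finger factors Egr2 (2.91 ± 0.51) and Egr3 (1.55 ± 0.21; its 2 probe sets were at 2.91 and 0.20) and the phosphatase gene Noct (2.77 ± 0.30) rose too. So did the AP-1 subunit Fosl1 (2.35 ± 0.47) and the matrix protein tenascin C, Tnc (2.20 ± 0.34). Hbegf, another ligand of the epidermal growth factor receptor, was named because a single probe set passed. Its mean over 2 probe sets was 2.71 ± 0.71 (adjusted p = 0.0529). Other falls were those of Pik3ip1 (-0.95 ± 0.22), an inhibitor of a lipid kinase of growth signalling, of the transglutaminase Tgm1 (-1.08 ± 0.18) and of Zfp775 (-1.08 ± 0.21). The methyltransferase gene Mettl21e (-1.01 ± 0.15), Olfm2 (-0.96 ± 0.16) and the F-box gene Fbxl8 (-0.95 ± 0.21) also fell. Smaller falls were those of the secreted protease Adamts10 (-0.58 ± 0.09; its 2 probe sets were at -1.03 and -0.14) and of the interferon-pathway factor Stat2 (-0.46 ± 0.09). The Stat2 change had the opposite sign, 0.030, with 1 probe set per gene. Bmf (-0.42 ± 0.13), Cyp1b1 (-0.46 ± 0.18) and Cwf19l1 (-0.25 ± 0.10) were likewise named from a single probe set. Their gene means missed the threshold at adjusted p = 0.102, 0.178 and 0.194.

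Among 28 gene lists fixed before the data were examined, 10 moved relative to other genes by camera, all of them upward. With an estimated correlation only 2 of these passed, and fry, which tests a list's own genes alone, called 9 lists (7 upward, 2 downward). In the immediate-early transcription factor list, 15 of 26 rose and 0 fell (19 and 0 adjusted over the list alone). Among them were Ier3 (2.47 ± 0.34) and the stress-responsive factor Atf3 (2.35 ± 0.49). Camera gave adjusted p = 1.45e-20 for this list, and adjusted p = 0.0638 with an estimated correlation. Feedback genes of the MAP kinase and FGF pathways followed, where 7 of 14 rose and 0 fell (9 and 0 adjusted over the list alone). Errfi1, an inhibitor of the epidermal growth factor receptor, rose by 2.23 ± 0.23, and the MAP kinase phosphatases Dusp5, Dusp6 and Dusp2 rose by 2.14 ± 0.27, 1.47 ± 0.22 and 1.23 ± 0.28. Of the targets of SRF, the actin cytoskeleton and YAP, 7 of 20 rose and 0 fell (9 and 0 adjusted over the list alone). They included Ankrd1 (1.03 ± 0.12), Srf itself (0.98 ± 0.21) and Fhl2 (0.64 ± 0.15). These 2 lists passed with the preset correlation (adjusted p = 2.19e-09 for each) and with an estimated one (adjusted p = 0.0159 and 0.0197).

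In the list of NF-kappaB targets and cytokines, 4 of 17 rose and 0 fell (6 and 0 adjusted over the list alone). Next to Ptgs2, they were Tnfaip3 (0.91 ± 0.21) and Nfkbia (0.82 ± 0.21), both negative regulators of NF-kappaB, and the cytokine Lif (0.58 ± 0.14). Camera gave adjusted p = 1.15e-06, and adjusted p = 0.0638 with an estimated correlation. Of the TGF-beta and BMP targets, 5 of 14 rose and 0 fell (7 and 1 adjusted over the list alone). Id2 (1.71 ± 0.27) and the inhibitory Smad gene Smad7 (1.44 ± 0.19) rose. The list test stood at adjusted p = 1.22e-05, or at adjusted p = 0.0986 with an estimated correlation. Cyclic genes of the mouse segmentation clock also moved upward, and 7 of 30 rose and 1 fell (10 and 2 adjusted over the list alone). The largest changes there were those of Id1, of the growth regulator Myc (2.34 ± 0.25), of Dusp6 and of the hyaluronan synthase Has2 (1.26 ± 0.27). All of these stand in other lists too. Id1 is among the TGF-beta and BMP targets, Myc among the immediate-early factors, Dusp6 among the MAP kinase feedback genes and Has2 in the extracellular matrix list. The shift is thus not separate from those lists, and the median change of the clock list was 0.11. The preset correlation gave adjusted p = 0.00249, and an estimated correlation gave adjusted p = 0.102. Within the Notch pathway, 0 of 18 rose and 1 fell (0 and 3 adjusted over the list alone). The called gene was the ligand gene Dll1 (-0.82 ± 0.10), and the list did not pass by camera (adjusted p = 0.471) but passed downward by fry (adjusted p = 0.0283).

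A smaller shift passed for the ribosome biogenesis and MYC target list, where 1 of 25 rose and 0 fell (1 and 0 adjusted over the list alone). The called gene was Heatr1 (0.54 ± 0.14). By camera, the list had adjusted p = 5.59e-04 (adjusted p = 0.655 with an estimated correlation). The endoplasmic reticulum stress list passed without a single called member, as 0 of 18 rose and 0 fell (0 and 0 adjusted over the list alone). Its members with the largest values were Herpud1 (0.91 ± 0.45), Hyou1 (0.53 ± 0.20), Dnajc3 (0.46 ± 0.20) and Dnajb9 (0.45 ± 0.25). This list had adjusted p = 0.00369 by camera and adjusted p = 0.655 with an estimated correlation. In the ATF4 and amino acid response list, 2 of 19 rose and 0 fell (3 and 0 adjusted over the list alone). These were the stress-induced factors Ddit3 (1.39 ± 0.35) and Atf4 (0.65 ± 0.10). Its test gave adjusted p = 0.0133, and adjusted p = 0.655 with an estimated correlation. The ATF4 call was also lost without the 2.0 h array (adjusted p = 0.155) and after quantile normalization (adjusted p = 0.0791). Fry called none of these 3 lists (adjusted p = 0.431 for each). Markers of blood and endothelial cells, cell types that the labels do not name, also passed, although 0 of 16 rose and 0 fell (0 and 0 adjusted over the list alone). Camera gave adjusted p = 0.0439, and adjusted p = 0.117 with an estimated correlation. Values there were 0.44 ± 0.13 for Adgre1, 0.33 ± 0.14 for Tyrobp, 0.30 ± 0.11 for Lyz2 and 0.26 ± 0.16 for Tie1. This call was lost without the 0.5 h array (adjusted p = 0.0748), without the 1.0 h array (adjusted p = 0.0696) and after quantile normalization (adjusted p = 0.0742).

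The remaining 17 lists besides the Notch pathway did not pass by camera in this comparison, and fry called 1 of them, the fibroblast markers, downward (adjusted p = 0.0224). Camera called some under alternatives. After quantile normalization, circadian clock genes (adjusted p = 0.0207) and G2 and M phase genes (adjusted p = 0.0362) passed upward. They also passed without the 2.0 h array (adjusted p = 0.0366 and 0.0200). Without the 0.5 h array, quiescence and FoxO targets passed downward (adjusted p = 0.0390). For the extracellular matrix, 4 of 27 rose and 0 fell (4 and 0 adjusted over the list alone). They included Timp3 (2.03 ± 0.36), an inhibitor of matrix proteases, and the secreted glycoprotein Thbs1 (1.24 ± 0.28). Of the circadian clock genes, 2 of 18 rose and 0 fell (3 and 1 adjusted over the list alone). These were the repressors Nfil3 (1.62 ± 0.22) and Bhlhe40 (1.56 ± 0.39). In the quiescence and FoxO list, 0 of 19 rose and 2 fell (0 and 2 adjusted over the list alone), Txnip and Pik3ip1. Among p53 targets, 1 of 12 rose and 0 fell (2 and 1 adjusted over the list alone), and the called gene was the kinase gene Plk2 (0.86 ± 0.16). For hypoxia and glycolysis, 1 of 16 rose and 0 fell (3 and 0 adjusted over the list alone), with the carbonic anhydrase Car9 at 0.58 ± 0.15. In the heat shock list, 1 of 13 rose and 0 fell (2 and 0 adjusted over the list alone), with the chaperone Hspa1b at 0.42 ± 0.11. Among interferon genes, 0 of 18 rose and 1 fell (0 and 1 adjusted over the list alone), the latter Stat2. Among fibroblast markers, 0 of 7 rose and 1 fell (0 and 2 adjusted over the list alone), and the called gene was the receptor gene Pdgfra (-0.42 ± 0.10).

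No member was called in the other lists. Among Wnt feedback genes and targets, 0 of 17 rose and 0 fell (0 and 1 adjusted over the list alone). Dact1 was at 0.56 ± 0.19, Dkk3 at -0.43 ± 0.12, Dkk2 at -0.35 ± 0.21 and Sp5 at -0.29 ± 0.12. In the STAT3 pathway, 0 of 11 rose and 0 fell (1 and 0 adjusted over the list alone). Socs2 (0.56 ± 0.14), Cish (0.35 ± 0.15), Socs3 (-0.21 ± 0.27) and Bcl3 (-0.17 ± 0.20) had the largest values. For genes of G1 and S phase, 0 of 23 rose and 0 fell (0 and 0 adjusted over the list alone). Ccne2 was at 0.66 ± 0.33, E2f2 at -0.37 ± 0.17 and Ccnd3 at -0.22 ± 0.08. Among genes of G2 and M phase, 0 of 23 rose and 0 fell (0 and 0 adjusted over the list alone). Cenpe was at 0.45 ± 0.17, Kif11 at 0.29 ± 0.11 and Aurkb at 0.27 ± 0.23. Among sterol synthesis genes, 0 of 19 rose and 0 fell (0 and 0 adjusted over the list alone), with Insig1 at 0.57 ± 0.39 and Dhcr7 at -0.43 ± 0.15. Among myoblast markers, 0 of 11 rose and 0 fell (0 and 0 adjusted over the list alone), with the cadherin Cdh15 at -0.37 ± 0.11 and Pax7 at -0.27 ± 0.23. Among genes of differentiated muscle, 0 of 28 rose and 0 fell (0 and 0 adjusted over the list alone), with Myh8 at -0.51 ± 0.20 and myoglobin, Mb, at -0.46 ± 0.13. For adipocyte and osteoblast markers, 0 of 10 rose and 0 fell (0 and 0 adjusted over the list alone), with Cebpa at -0.57 ± 0.22. For housekeeping genes, 0 of 9 rose and 0 fell (0 and 0 adjusted over the list alone), with Ywhaz at 0.31 ± 0.14 and Polr2a at -0.25 ± 0.21. List median, mean and test differed in sign for the Wnt, heat shock and STAT3 lists.

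Over all probe sets, 1361 of 45037 passed (704 higher, 657 lower; limma, Benjamini-Hochberg), or 594 of 18193 genes (265 higher, 329 lower). An absolute log2 change of 1 was also reached by 161 of the probe sets (151 higher, 10 lower). All of these values rest on a single 0 h array. Quantile normalization, which gives every array the same spread, left 93 probe sets (82 higher, 11 lower). It ended 30 of the 48 named calls, that of Txnip among them. An early window of 0.5 to 1.5 h left 538 probe sets and ended 13 named calls, as did the fit without the 2.5 to 4.0 h arrays. The variance trend with a robust prior ended 6, that of Nr4a1 among them. Leaving out 1 array gave 738 probe sets (without 1.5 h), 877 (without 5.0 h), 886 (without 5.5 h) or 2841 (without 0.5 h). The named calls of Ankrd1, Ccn2, Dll1, Dusp6, Egr2, Errfi1, Id3, Ier3, Myc, Nfil3, Noct, Plk2, Ptgs2 and Smad7 held in every setting that was run. With 1 probe set per gene, 9 of the 48 named calls were lost, those of Adamts10, Atf4, Ddit3, Egr3, Heatr1, Hspa1b, Id2, Pdgfra and Pik3ip1. Leaving out a single array ended the calls of 15 named genes (Bhlhe40, Car9, Ddit3, Dusp2, Fbxl8, Fhl2, Heatr1, Hspa1b, Lif, Nfkbia, Pdgfra, Pik3ip1, Srf, Thbs1 and Tnfaip3), at adjusted p values from 0.0502 to 0.0849. Of these, Ddit3, Heatr1, Hspa1b, Pdgfra and Pik3ip1 were also lost with 1 probe set per gene.

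**Figure D1:**
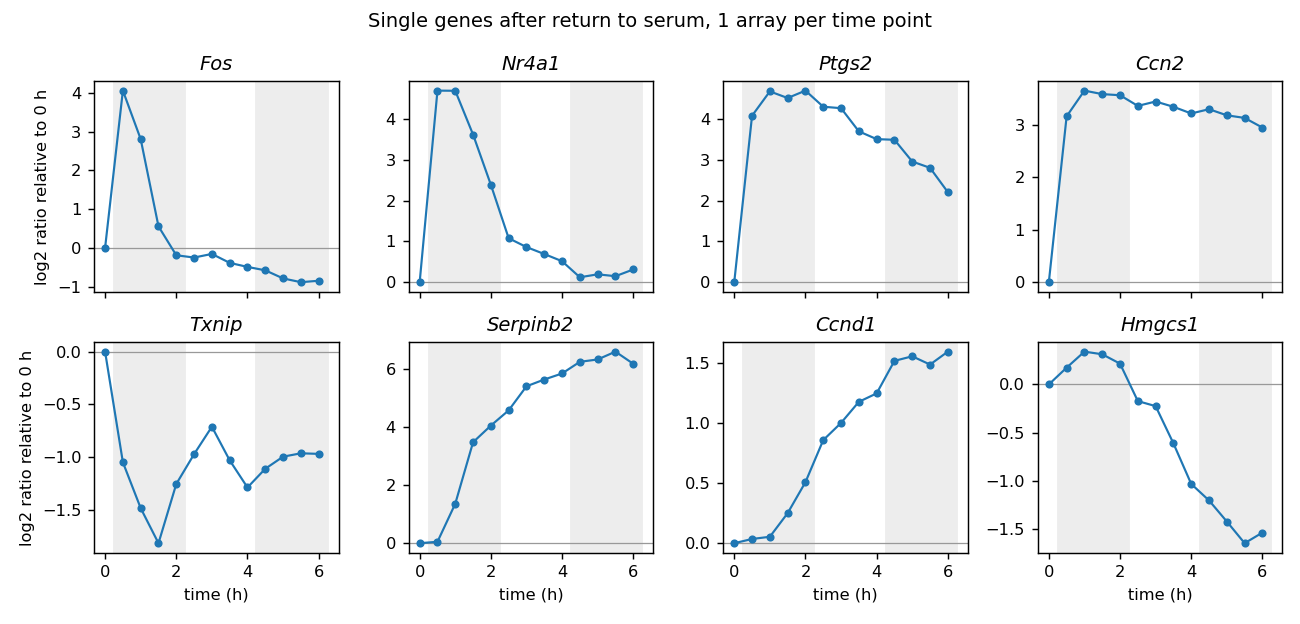
Log2 level relative to the 0 h array (vertical axis) against time after the return to serum in hours (horizontal axis) for 8 named genes, 1 point per array. Grey bands mark the early and late windows; Nr4a1 was highest at 0.5 h, Ptgs2 at 2.0 h and Serpinb2 at 5.5 h, while Txnip was lowest at 1.5 h.

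The second comparison asked what changed from the early to the late window. By camera, the immediate-early and sterol synthesis lists moved downward, and the ribosome biogenesis, ATF4 and amino acid response, and G1 and S phase lists moved upward. With an estimated correlation none of these 5 passed (adjusted p from 0.105 to 0.22). Serpinb2, an inhibitor of plasminogen activators, rose most among the named genes, by 4.11 ± 0.63 (adjusted p = 3.59e-04), and stood 97.9-fold over 0 h at 5.5 h. The replication licensing factor Cdc6 rose by 1.69 ± 0.21 (adjusted p = 7.74e-05), and Hmgcs1, an early enzyme of cholesterol synthesis, fell by 1.72 ± 0.15 (adjusted p = 1.12e-05). Nr4a1 fell by 3.66 ± 0.37 (adjusted p = 2.18e-05). The 5′ control probe set of 18S ribosomal RNA, which was not tested, also changed over the course, though not evenly. Its ratio was 0.849 at 0 h and 0.411 to 1.40 in the early window. It was 0.454, 0.397, 1.24 and 2.14 on the middle arrays and 0.889, 3.92, 2.67 and 5.24 on the 4 late arrays.

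Other large rises were those of Gpr176 (2.01 ± 0.21), an orphan G protein-coupled receptor, and of the potassium channel Kcnk2 (1.96 ± 0.16). Dctd (1.87 ± 0.12), which deaminates dCMP on the way to thymidine nucleotides, and the uracil-DNA glycosylase Ung (1.84 ± 0.20) rose too. They were followed by Dynap (1.74 ± 0.19), the branched-chain aminotransferase Bcat1 (1.22 ± 0.16) and the adhesion molecule Alcam (1.13 ± 0.08). Gm2115 (1.13 ± 0.08), the chromatin protein Hmga2 (1.12 ± 0.24) and Cdca7 (1.06 ± 0.09) completed the group. Large falls included those of the AP-1 subunits Fos (-2.58 ± 0.64) and Fosb (-2.52 ± 0.40) and of Atf3 (-2.62 ± 0.31), Egr2 (-2.77 ± 0.32), Egr3 (-1.38 ± 0.13) and the activity-regulated gene Arc (-2.25 ± 0.16). The Egr3 value is a mean over probe sets at -2.43 and -0.32. The chemokine Cxcl1 (-1.30 ± 0.27), Nrep (-1.78 ± 0.20) and the engulfment adaptor Gulp1 (-1.62 ± 0.16) also fell. Tnc fell as a mean over its probe sets (-0.97 ± 0.22). With 1 probe set per gene it had a value of 0.84, which passed in the opposite direction (limma, adjusted p = 0.0103).

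By camera, 19 of the 28 lists passed, 5 upward and 14 downward. With an estimated correlation 0 passed, so the adjusted p from that estimate stands beside each. Fry called 22 lists (6 upward, 16 downward), these 19 among them. Ribosome biogenesis and MYC targets rose nearly as a whole: 24 of 25 rose and 0 fell (24 and 0 adjusted over the list alone). The list test stood at adjusted p = 2.26e-17, or at adjusted p = 0.109 with an estimated correlation. Dkc1, the pseudouridine synthase of small nucleolar RNPs, rose by 1.52 ± 0.15, and the nucleolar genes Nop56, Rrp12 and Nop16 rose by 1.22 ± 0.15, 1.06 ± 0.16 and 1.03 ± 0.14. Of the G1 and S phase genes, 17 of 23 rose and 0 fell (19 and 0 adjusted over the list alone). The cyclins Ccnd1 (1.33 ± 0.10) and Ccne2 (1.28 ± 0.21) and the licensing factor Cdt1 (0.94 ± 0.10) were among them. The preset correlation gave adjusted p = 3.66e-12, and an estimated correlation gave adjusted p = 0.105. G2 and M phase genes went the other way, where 0 of 23 rose and 20 fell (0 and 21 adjusted over the list alone). By camera, the list had adjusted p = 3.65e-15 (adjusted p = 0.105 with an estimated correlation). The proliferation marker Mki67 (-0.98 ± 0.13), the mitotic cyclin Ccnb2 (-0.82 ± 0.08), the kinetochore motor Cenpe (-0.64 ± 0.11) and Hmmr (-0.60 ± 0.10) fell, and Hmmr had a value of 0.044 with 1 probe set per gene.

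The ATF4 and amino acid response list moved upward, and 11 of 19 rose and 2 fell (12 and 2 adjusted over the list alone). This list had adjusted p = 5.25e-05 by camera and adjusted p = 0.22 with an estimated correlation. Asparagine synthetase, Asns, rose by 1.55 ± 0.18, the mitochondrial folate enzyme Mthfd2 by 1.22 ± 0.21, Psph of serine synthesis by 1.22 ± 0.14 and Cth of cysteine synthesis by 1.21 ± 0.15. In the endoplasmic reticulum stress list, 10 of 18 rose and 0 fell (10 and 0 adjusted over the list alone), including Creld2 (1.07 ± 0.17), Sdf2l1 (0.79 ± 0.15), Manf (0.68 ± 0.12) and Dnajb11 (0.57 ± 0.09). Its test gave adjusted p = 0.00271, and adjusted p = 0.446 with an estimated correlation. Genes of differentiated muscle also moved upward, as 19 of 28 rose and 1 fell (19 and 1 adjusted over the list alone). Camera gave adjusted p = 3.28e-06, and adjusted p = 0.22 with an estimated correlation. They included caveolin 3, Cav3 (0.67 ± 0.14), the troponin C genes Tnnc1 (0.63 ± 0.11) and Tnnc2 (0.57 ± 0.12) and the calcium-binding calsequestrin Casq2 (0.57 ± 0.13). Sterol synthesis and SREBP2 targets fell almost without exception, since 1 of 19 rose and 18 fell (1 and 18 adjusted over the list alone). The list test stood at adjusted p = 2.26e-17, or at adjusted p = 0.105 with an estimated correlation. The SREBP regulator Insig1 (-1.80 ± 0.25), the sterol carrier Stard4 (-1.40 ± 0.17) and the mevalonate pathway enzyme Mvd (-1.20 ± 0.13) fell together with Hmgcs1.

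Signalling lists fell by camera. For the immediate-early factors, 0 of 26 rose and 22 fell (0 and 22 adjusted over the list alone). The preset correlation gave adjusted p = 1.63e-18, and an estimated correlation gave adjusted p = 0.105. In the MAP kinase and FGF feedback list, 2 of 14 rose and 7 fell (2 and 7 adjusted over the list alone). It held falls of Errfi1 (-1.28 ± 0.15), Dusp2 (-1.03 ± 0.18), Phlda1 (-0.75 ± 0.09) and Dusp5 (-0.73 ± 0.17). By camera, the list had adjusted p = 0.00264 (adjusted p = 0.105 with an estimated correlation). Among NF-kappaB targets and cytokines, 0 of 17 rose and 10 fell (0 and 11 adjusted over the list alone). Ptgs2 (-1.63 ± 0.24), the chemokine Ccl2 (-1.40 ± 0.34) and Tnfaip3 (-0.63 ± 0.13) fell. This list had adjusted p = 5.25e-05 by camera and adjusted p = 0.105 with an estimated correlation. Of the TGF-beta and BMP targets, 0 of 14 rose and 5 fell (0 and 7 adjusted over the list alone). Id3 was at -1.47 ± 0.17, Id1 at -1.11 ± 0.32, Skil at -0.63 ± 0.17 and Smad7 at -0.62 ± 0.12. Its test gave adjusted p = 0.00271, and adjusted p = 0.176 with an estimated correlation. In the segmentation clock list, 1 of 30 rose and 12 fell (1 and 12 adjusted over the list alone). Egr1 (-1.98 ± 0.31), which is also in the immediate-early list, and the Notch target Heyl (-1.32 ± 0.13) fell. Camera gave adjusted p = 0.00117, and adjusted p = 0.105 with an estimated correlation. In the STAT3 list, 0 of 11 rose and 3 fell (0 and 4 adjusted over the list alone). The receptor Lifr (-0.48 ± 0.07), Stat3 (-0.45 ± 0.08) and the kinase Pim1 (-0.27 ± 0.09) fell. The list test stood at adjusted p = 0.00375, or at adjusted p = 0.149 with an estimated correlation. With 1 probe set per gene this call was lost (adjusted p = 0.0615).

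Quiescence and FoxO targets were lower as well, where 0 of 19 rose and 7 fell (1 and 10 adjusted over the list alone). The preset correlation gave adjusted p = 2.18e-05, and an estimated correlation gave adjusted p = 0.203. Sesn3 (-1.44 ± 0.13), an inhibitor of TORC1 signalling, the mitophagy receptor Bnip3 (-1.23 ± 0.11), the ubiquitin ligase component Fbxo32 (-0.81 ± 0.15) and the transcriptional regulator Cited2 (-0.77 ± 0.12) led the list. Of the circadian clock genes, 0 of 18 rose and 9 fell (1 and 9 adjusted over the list alone). Bhlhe40 (-1.06 ± 0.25), Nfil3 (-1.05 ± 0.14), Dbp (-0.80 ± 0.15) and Per1 (-0.74 ± 0.13) fell most. By camera, the list had adjusted p = 4.90e-04 (adjusted p = 0.0964 with an estimated correlation). In the extracellular matrix list, 2 of 27 rose and 12 fell (2 and 13 adjusted over the list alone). This list had adjusted p = 4.90e-04 by camera and adjusted p = 0.149 with an estimated correlation. Fibronectin, Fn1 (-0.98 ± 0.17; its 2 probe sets were at -1.80 and -0.15), and Thbs1 (-0.98 ± 0.18) fell and the protease inhibitor Timp1 (1.01 ± 0.15) rose. Among hypoxia and glycolysis genes, 1 of 16 rose and 5 fell (2 and 6 adjusted over the list alone). Ndrg1 was at -1.09 ± 0.13, the pyruvate dehydrogenase kinase Pdk1 at -0.72 ± 0.08, Ddit4 at -0.64 ± 0.15 and the oxygen sensor Egln3 at 0.54 ± 0.09. Its test gave adjusted p = 0.0141, and adjusted p = 0.176 with an estimated correlation. The call was lost with 1 probe set per gene (adjusted p = 0.107).

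Directions were mixed within the SRF and p53 lists. Of the SRF, actin cytoskeleton and YAP targets, 2 of 20 rose and 7 fell (2 and 8 adjusted over the list alone). Camera gave adjusted p = 0.0333, and adjusted p = 0.22 with an estimated correlation. The actin-binding gene Tagln rose by 1.25 ± 0.15, while Filip1l (-0.63 ± 0.18) and Srf (-0.62 ± 0.14) fell. Actb fell as a mean (-0.39 ± 0.11), but 1 of its 2 probe sets was at -0.81 and the other at 0.04. The array's Actb control probe sets, which were not tested, did not show this fall. In deposited log2 ratio, the 5′ one lay between 0 and 0.08 early and between 0.03 and 0.18 late, and the 3′ one between -0.05 and 0.03 early and between 0 and 0.13 late. The list's call was lost without the 4.5 h array (adjusted p = 0.0738), without the 6.0 h array (adjusted p = 0.0653), after quantile normalization (adjusted p = 0.0928) and with 1 probe set per gene (adjusted p = 0.127). For the p53 targets, 2 of 12 rose and 3 fell (2 and 3 adjusted over the list alone). The list test stood at adjusted p = 0.0485, or at adjusted p = 0.149 with an estimated correlation. Plk2 (-0.55 ± 0.10) and the cell death gene Pmaip1 (-0.38 ± 0.07) fell, and Ei24 (0.37 ± 0.07) and Phlda3 (0.33 ± 0.10) rose. Leaving out the 1.5, 2.0, 3.0, 4.5 or 5.0 h array ended that call (adjusted p = 0.0515, 0.0877, 0.0504, 0.0778 and 0.0549). So did quantile normalization (adjusted p = 0.087), 1 probe set per gene (adjusted p = 0.0639) and removal of floor-scaled probe sets (adjusted p = 0.0568).

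The other 9 lists did not pass by camera. Fry called 3 of them, the Notch pathway (downward, adjusted p = 0.00758), Wnt feedback and targets (upward, adjusted p = 2.31e-04) and adipocyte and osteoblast markers (downward, adjusted p = 0.0104). In the Notch pathway, 1 of 18 rose and 5 fell (1 and 5 adjusted over the list alone). The receptors Notch3 (-0.90 ± 0.19) and Notch2 (-0.58 ± 0.08), Heyl and the glycosyltransferase Lfng (-0.42 ± 0.13) fell. For Wnt feedback and targets, 3 of 17 rose and 1 fell (3 and 2 adjusted over the list alone). Ccnd1, Dkk2 (0.49 ± 0.13) and Znrf3 (0.33 ± 0.09) rose and Dact1 (-0.54 ± 0.12) fell. Among heat shock genes, 5 of 13 rose and 3 fell (6 and 4 adjusted over the list alone). The mitochondrial chaperones Hspd1 (0.78 ± 0.08) and Hspe1 (0.46 ± 0.11) and Hsph1 (0.49 ± 0.07) rose, and the co-chaperone Bag3 (-0.53 ± 0.10) fell. Among myoblast markers, 1 of 11 rose and 0 fell (1 and 0 adjusted over the list alone), with Msc at 0.30 ± 0.06. Among interferon genes, 1 of 18 rose and 2 fell (1 and 2 adjusted over the list alone), which were Usp18 (0.60 ± 0.12), Gbp2 (-0.74 ± 0.07) and Oasl2 (-0.40 ± 0.12). Of the adipocyte and osteoblast markers, 0 of 10 rose and 1 fell (0 and 1 adjusted over the list alone), with Lpl at -0.54 ± 0.07. Of the blood and endothelial markers, 0 of 16 rose and 1 fell (0 and 0 adjusted over the list alone), with Tek at -0.28 ± 0.08. Of the fibroblast markers, 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone), with Twist2 at 0.93 ± 0.12 and Pdgfrb at -0.55 ± 0.13. Of the housekeeping genes, 1 of 9 rose and 1 fell (1 and 1 adjusted over the list alone), Hprt (0.29 ± 0.07) and Polr2a (-0.45 ± 0.13). Median, mean and test differed in sign for the Notch, heat shock, myoblast, blood and endothelial, fibroblast and housekeeping lists.

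In all, 6902 of 45037 probe sets passed (3639 higher, 3263 lower; limma, Benjamini-Hochberg), or 3827 of 18193 genes (2137 higher, 1690 lower). Of the probe sets, 336 also reached an absolute log2 change of 1 (138 higher, 198 lower). Both window comparisons used the same 4 early arrays, so they are not independent. Of the 110 named calls, 85 held in every setting that was run. Windows of 0.5 to 1.5 h and 5.0 to 6.0 h ended 13, and a straight line in time ended 10. Both ended those of Dact1, Ddit4, Dkk2, Msc, Oasl2, Pmaip1, Skil, Tek and Znrf3. The narrower windows also ended those of Actb, Ccl2, Id1 and Lfng, and the straight line that of Filip1l. With 1 probe set per gene 7 were lost, among them those of Fn1, Lifr, Notch2, Pdgfrb, Pim1 and Stat3. Leaving out a single array ended those of Actb, Dkk2, Filip1l, Id1, Lfng, Oasl2, Phlda3, Pim1, Polr2a, Tek and Znrf3, at adjusted p values from 0.0501 to 0.153.

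**Figure D2:**
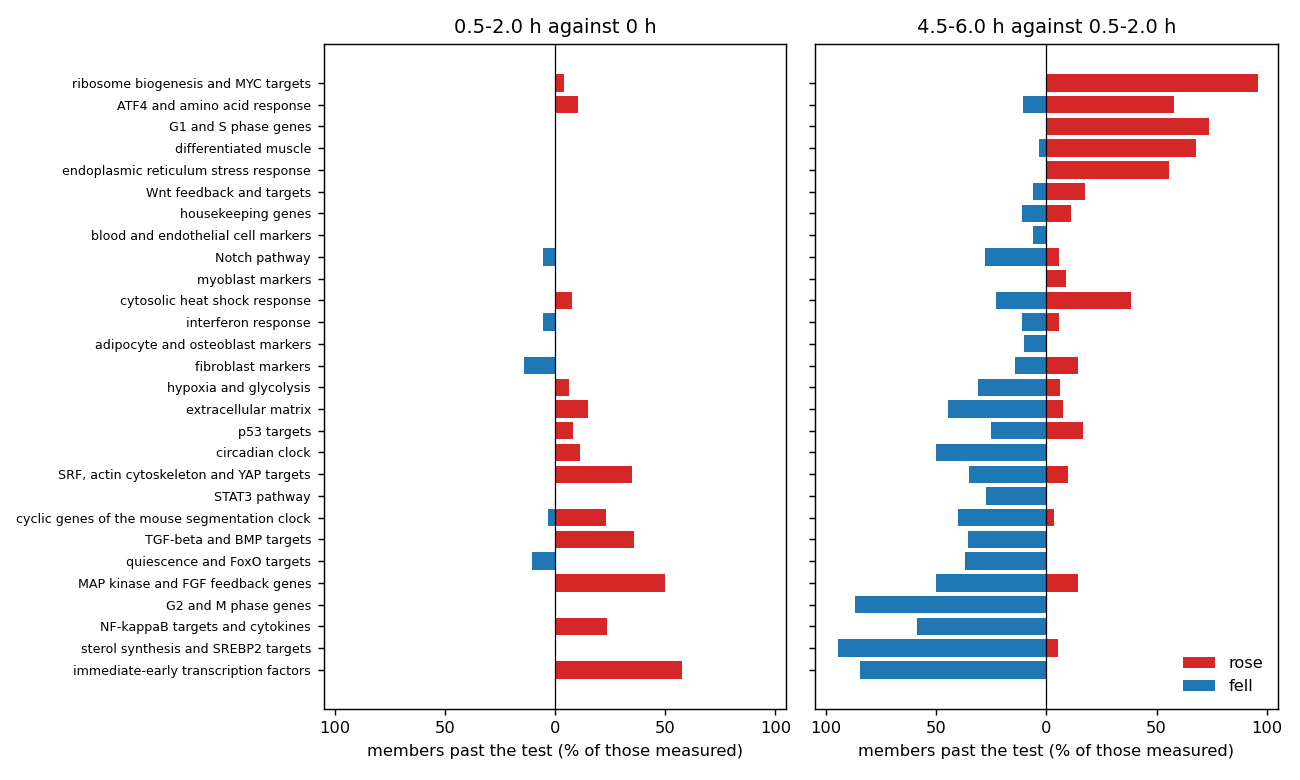
Percent of the measured members of each of the 28 gene lists that rose or fell (horizontal axis, from 0) in the early against 0 h and the late against early comparison. In the late against early comparison 24 of 25 ribosome biogenesis genes rose and 18 of 19 sterol genes fell.

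The third comparison asked which genes followed any smooth course over the 13 arrays, without windows. The 10 genes with the smallest p over single probe sets were Hbegf, Nrep, Ereg, Fosl1, Ung, Tagln, Serpinb2, Pxylp1, Kcnn4 and Msmo1. The growth factor receptor ligands Hbegf and Ereg were both highest at 2.0 h, at 14.9 and 21.4 times the 0 h level (adjusted p = 2.68e-09 and 1.92e-09). Fosl1 was highest at 2.0 h, 8.3-fold over 0 h (adjusted p = 3.72e-09). Kcnn4, a calcium-activated potassium channel, was highest at 5.0 h (2.6-fold; adjusted p = 3.82e-08). Ung, Tagln and Serpinb2 were highest at 6.0, 5.5 and 5.5 h (adjusted p = 1.51e-09, 1.46e-09 and 5.90e-09). Pxylp1 was lowest at 3.5 h, 2.3-fold under 0 h (adjusted p = 1.29e-07), Nrep at 4.5 h, 5.18-fold under 0 h (adjusted p = 1.46e-09), and the sterol enzyme Msmo1 at 6.0 h, 2.41-fold under 0 h (adjusted p = 3.93e-08).

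Relative to 0 h, the median of the immediate-early list was highest at 1.0 h (1.79) and that of the MAP kinase and FGF feedback list also at 1.0 h (0.93), while NF-kappaB targets were highest at 1.5 h (0.53). Quiescence and FoxO targets were lowest at 3.5 h (-0.95). The G1 and S phase median stood at 0.09 at 4.0 h, 0.41 at 4.5 h and 0.81 at 6.0 h, and ribosome biogenesis was highest at 5.5 h (1.01). Sterol synthesis was lowest at 6.0 h (-0.96), and ATF4 targets were highest then (0.87). The endoplasmic reticulum stress median stood at -0.07 at 0.5 h and 0.36 at 2.0 h. It was highest at 3.0 h (0.47), before the late window, and stood at 0.43 at 6.0 h. The spline test called 13815 of 45037 probe sets (30.7%; limma moderated F, Benjamini-Hochberg) and 6911 of 18193 genes (38.0%). Of these genes, 1545 were highest at 0 h and 1264 at 6.0 h, and 1002 were lowest at 0 h.

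**Figure D3:**
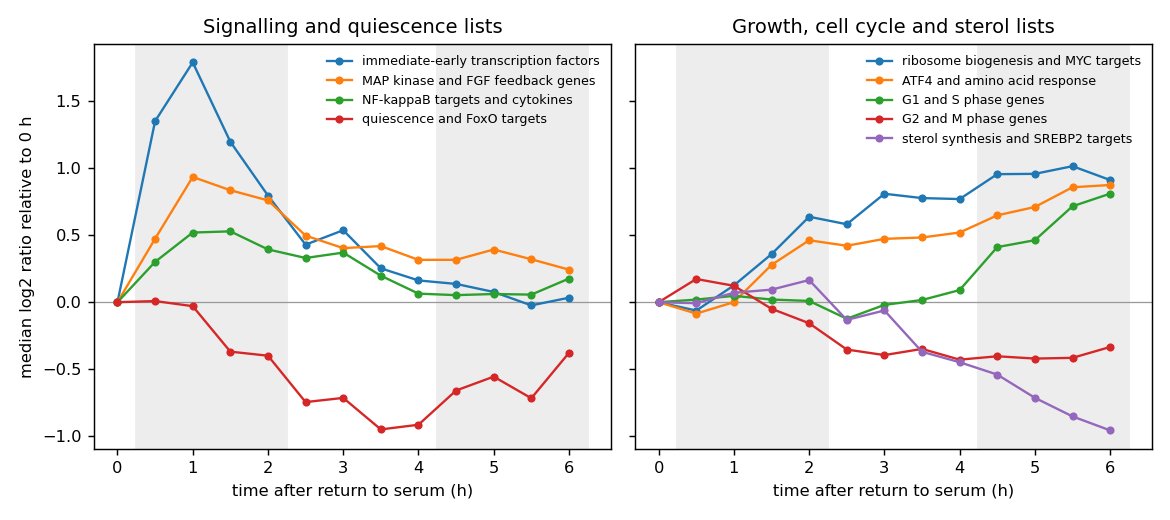
Median log2 level of the members of selected gene lists relative to the 0 h array (vertical axis) against time after the return to serum in hours (horizontal axis), 1 point per array. The immediate-early median was highest at 1.0 h (1.79), and the sterol median was lowest at 6.0 h (-0.96).

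The last comparison asked which genes oscillated with a period of 2 h, the known period of Hes1 in serum-stimulated mouse cells. Hes1, a Notch-regulated repressor of the segmentation clock, had an amplitude of 0.40 ± 0.11 with a peak at 1.09 h (adjusted p = 0.998). Its level was 2.58-fold over 0 h at 1.0 h and 1.32-fold under it at 2.0 h. The related repressor Hey1 had an amplitude of 0.17 ± 0.04 with a peak at 1.77 h (adjusted p = 0.998), and Id1 one of 0.37 ± 0.13 with a peak at 1.01 h (adjusted p = 0.998).

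The limma F test called 0 of 45037 probe sets (smallest adjusted p = 0.999), with 1716 (3.8%) at an unadjusted p under 0.05. It called 0 of 18193 genes, with 721 at an unadjusted p under 0.05. Periods of 1.5 and 2.5 h, a linear trend and a more flexible trend also gave 0 probe sets, while a period of 3.0 h gave 142 and leaving out the 2.5 to 4.0 h arrays gave 11. In simulated data, 37.3% of oscillations with an amplitude of 0.25 on the log2 scale, 92.5% of those of 0.5 and 100% of those of 1 were called. Amplitudes had a median standard error of 0.0401 over genes, so smaller swings such as that of Hey1 were often not detectable with these arrays. The standard errors of Hes1 (0.112) and Id1 (0.128) were larger. The simulated rates, from probe sets picked at random, need not hold for such genes.

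Of the 30 segmentation clock genes, 3 (Hey1, Hes1 and Id1) had an unadjusted p under 0.05 and 0 passed over all genes or adjusted over the list alone. Egr1 (0.24 ± 0.15), Myc (0.22 ± 0.13), Dusp6 (0.19 ± 0.08), Phlda1 (0.16 ± 0.10), Snai1 (0.13 ± 0.06), Ccn1 (0.12 ± 0.21), Hes5 (0.10 ± 0.05), Efna1 (0.10 ± 0.08) and Snai2 (0.10 ± 0.05) had the next largest amplitudes. Those of Hspg2, Heyl, Lfng, Nrarp, Spry2, Axin2, Has2, Hes7, Dusp4, Bcl2l11, Sp5, Dll1, Spry4, Tnfrsf19, Nkd1, Dact1, Dkk1 and Ptpn11 lay between 0.02 ± 0.04 (Ptpn11) and 0.09 ± 0.04 (Hspg2). The list's median F was 1.03 against 0.891 with permuted array order (permutation test, p = 0.383, adjusted p = 0.754). For the Notch pathway it was 0.722 against 0.732 (permutation test, p = 0.514, adjusted p = 0.769).

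The other 26 lists did not pass either, at adjusted permutation p values from 0.754 to 0.918. Adjusted over the list alone, 1 gene passed in the Wnt list, the secreted Wnt regulator Dkk2 (amplitude 0.20 ± 0.04), 1 in the blood and endothelial list, the macrophage marker Cd68 (0.18 ± 0.04), and 0 in each of the other lists. Further list members with large F were the cell cycle inhibitor Cdkn1b (0.18 ± 0.04), Casq2 (0.16 ± 0.04), the muscle determination factor Myf5 (0.21 ± 0.06), Pim1 (0.12 ± 0.03), Bcl6 (0.19 ± 0.05), Emcn (0.14 ± 0.04), Irs2 (0.19 ± 0.06) and the phosphatase Dusp1 (0.40 ± 0.15). The 10 genes with the smallest p over single probe sets were Fam110b, Cryl1, Plekhh1, Klf12, Nisch, Srr, Edn3, Zfhx4, Cep135 and Sim1, whose gene-level amplitudes ran from 0.02 ± 0.03 (Klf12) to 0.28 ± 0.06 (Zfhx4), each at adjusted p = 0.998.

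**Figure D4:**
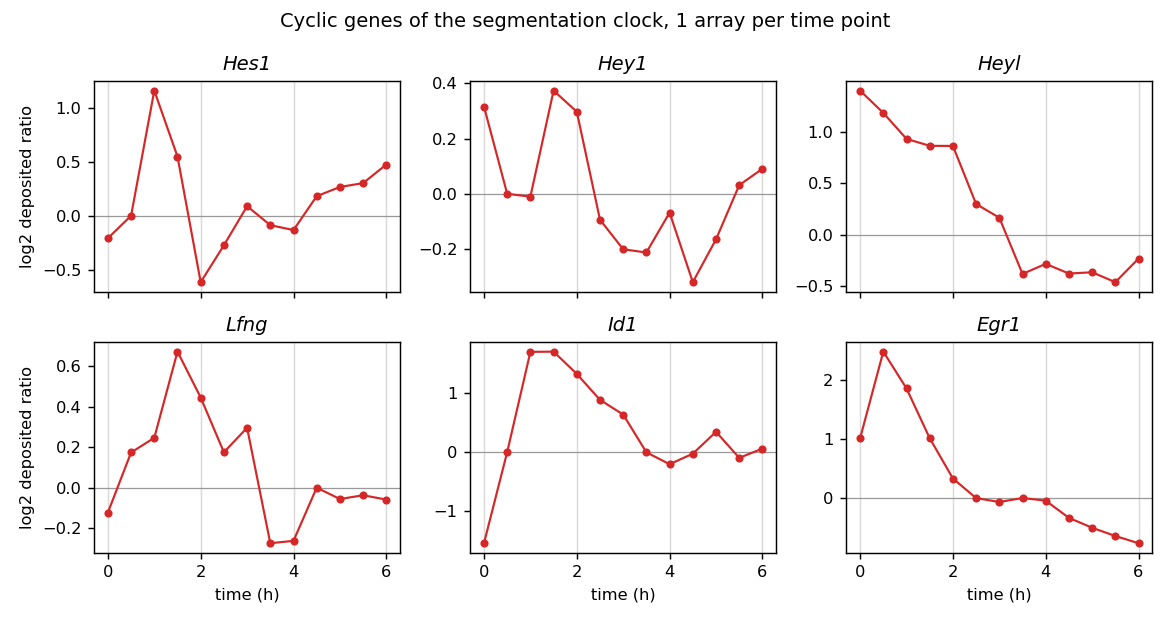
Log2 of the deposited ratio (vertical axis) against time after the return to serum in hours (horizontal axis) for 6 segmentation clock genes, 1 point per array. Hes1 was highest at 1.0 h and lowest at 2.0 h, and Heyl and Lfng were lower in the late than in the early window.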

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

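Comparing the control probe sets with the 0 h array was chosen only after their values had been seen. The control probe sets, which no comparison uses, held a signal above the 0 h array for 18S ribosomal RNA: the 5′ probe set was 6.17-fold over 0 h at 6.0 h and the 3′ probe set 2.15-fold. The middle 18S probe set reached 1.77-fold at 5.0 h, the poly-A spikes 1.37-fold at 5.5 h, the hybridisation spikes 1.16-fold at 0.5 h, and the 5′ and 3′ probe sets of Gapdh and Actb stayed within 1.16-fold above 0 h. The 5′ probe set of 18S was already at a ratio of 2.14 at 4.0 h, and at 0.889 at 4.5 h, so its rise was not even.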

How the results depend on the processing

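Chosen only after the data were examined were the tests without floor-scaled probe sets, without the 2.5 to 4.0 h arrays, with 1 mean value per gene and with 1 probe set per gene. The count of probe sets past the threshold for early against 0 h went from 1361 to 93 after quantile normalization, to 538 with an early window of 0.5 to 1.5 h, to 161 with a log2 change of 1 or more and to 594 genes. Leaving out 1 array gave 738 (without 1.5 h) to 2841 (without 0.5 h), with 877 without 5.0 h and 886 without 5.5 h. Late against early went from 6902 to 336 with a log2 change of 1 or more and to 3827 genes, with 5429 to 7035 when 1 array was left out, and the smooth course from 13815 to 6911 genes, with 11811 to 13827. The oscillation count of 0 went to 142 at a period of 3.0 h and to 11 without the 2.5 to 4.0 h arrays, and stayed at 0 with each array left out. A minimum change and fewer tested genes lower a count by construction. Quantile normalization gives every array the same spread. The deposited log2 ratios spread most at 0 h (SD 0.318 over probe sets, against 0.188 at 5.0 h), so it narrows the 0 h array by construction. How much of the drop to 93 comes from this was not tested. For the other settings the cause was not tested. With an estimated correlation, 2 of 10 lists passed for early against 0 h and 0 of 19 for late against early; fry called 9 and 22 lists. At a period of 3.0 h, 2 lists passed the oscillation test, ATF4 and amino acid response and myoblast markers. Lists past the threshold numbered 9 to 11 and 17 to 19 when 1 array was left out. With 1 probe set per gene, reversed directions were 0.030 for Stat2 (early against 0 h), 0.84 for Tnc and 0.044 for Hmmr (late against early); the cause was not tested. Over all settings, values of named genes and lists kept their side of the threshold in 8867 cases, lost it in 280 and gained it in 44. A reversal was counted in 3 cases, while 117 counts stayed within 1.5 times and 16 moved. The 8867 include changes of sign where neither value passed. They also include amplitudes and F values, which cannot reverse. Planned filters on low values were not run, since the ratios hold no level, and signal over background is unknown for the same reason. No paired analysis was possible because each time point had 1 array and the labels carry no replicate numbers.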

Other observations

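Of the tests in this part, the grouping of genes by symbol stem, the count over every order of arrays within windows, and the fits of Hes1, Hey1 and Id1 to the later arrays were chosen only after the results they measure had been seen. Beyond the fixed lists, genes were grouped by the stem of their symbol into 244 families of at least 10 genes. By camera, 0 families moved for early against 0 h and 17 for late against early, 11 upward and 6 downward, and none passed with an estimated correlation (lowest adjusted p = 0.791). The medians of these 17 kept their sign under each scaling, where camera was not rerun. Mitochondrial ribosomal proteins rose in part: 21 of 47 Mrpl genes (median 0.17, adjusted p = 2.07e-06) and 17 of 29 Mrps genes (median 0.23, adjusted p = 2.38e-06), with 0 and 0 falling. So did 9 of 10 Exosc genes of the RNA exosome (median 0.31, adjusted p = 4.20e-04), 9 of 15 Timm genes of mitochondrial protein import (median 0.22, adjusted p = 8.79e-04) and 7 of 12 Alg genes of protein glycosylation (median 0.20, adjusted p = 0.00398). Among Eif translation factors 16 of 47 rose and 2 fell (adjusted p = 0.00469), and among RNA polymerase subunits of the Polr stem 12 of 25 rose and 3 fell (adjusted p = 0.00469).

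Downward, 13 of 38 Kif genes, which encode kinesin motors, fell and 0 rose (median -0.05, adjusted p = 0.00469). Of the Ift genes of transport within cilia, 6 of 15 fell and 0 rose (median -0.14, adjusted p = 0.00398).

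The 6902 probe sets called for late against early could come from array processing in blocks that match the windows, from chance or from time in serum. Blocks alone would leave time trends within windows unrelated to the change, but 86.6% of the called probe sets had a slope within windows in the direction of the change, against 13.4% to 86.2% in 99 shuffled orders. By window, the share was 73.6% early, 82.4% in the middle and 59.4% late. Over all 13824 orders within windows, 17 (0.123%, the real one included) gave as high a share, which counts against blocks as the only cause. Still, the lowest correlations of neighbouring arrays lay on the window borders (0.263 for 2.0 and 2.5 h, 0.317 for 4.0 and 4.5 h, others 0.38 or more). Only 1 of the 35 splits of the 8 arrays gave as many calls, the real one, and the highest other gave 0. Likewise the 13815 calls of the smooth course came from 1 of 100 array orders, with 1934 as the highest other. These counts argue against a grouping unrelated to time. They cannot exclude chance, because the splits are few and shuffling ignores that neighbouring arrays resemble each other. Chance in an ordered series, blocks that added to a trend, a gradual drift in processing in the order of collection, and time in serum itself stay open, since each time point had 1 array.

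At a period of 3.0 h, 142 probe sets passed. Only 1 of 100 orders of the residuals, the real one, gave as many, with 32 as the highest other. Chance cannot be excluded by this. Shuffling ignores that neighbouring arrays resemble each other, and the shuffled orders do not repeat the choice among the periods tried. A candidate explanation is the rise and fall of the first 2 h after serum, read as a wave. Fitted to 2.0 to 6.0 h alone, the median share of the amplitude left at the same phase was 0.361. It was under 0.5 for 91 of the 142, as that explanation predicted for the median, and 0.75 or more for 15. The share cannot decide, because the later fit used a linear trend in place of the spline. The 142 had also been chosen by the fit to the whole course, which favours a smaller amplitude in a part of it. Both that explanation and a repeated wave stay open, as hypotheses. The genes with the smallest p at this period, chosen after their values were seen, included Trps1 and Enpp3, whose shares left were 0.506 to 0.604 (3 probe sets) and 0.788 (1 probe set).

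Hes1 was highest at 1.0 h and was lowest at 2.0 h, which could be a single pulse after serum or the first turn of an oscillation every 2 h. Along its phase in the whole course, its amplitude on 2.0 to 6.0 h alone was 0.12 ± 0.05 (standard error), 0.295 of that in the whole course. A single pulse would leave a low share, but the value lay over 2 standard errors above 0. This fit also kept the 2.0 h array, where Hes1 was lowest, and used a linear trend in place of the spline. Either could move the value, so pulse and oscillation cannot be told apart with 9 arrays and 1 per time point. Hey1 kept 0.16 ± 0.07 of its 0.17, and as its adjusted p was 0.998 over all genes, whether it oscillates stays a hypothesis. Id1 kept 0.02 ± 0.13 of its 0.37, a low share as a pulse would leave. The trend changed between the fits there too, so an oscillation of Id1 stays open.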
